A study of Oryza sativa with 2 samples.

How the data were processed

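Total RNA from leaves of 2-week-old rice seedlings was sequenced as strand-specific libraries, per the labels' protocols, with 1 library from nontransgenic plants (NT) and 1 from plants labelled PGD1:Roc10. Seeds were germinated at 28 °C for 4 days and seedlings were then grown in soil with 3 plants per pot. The labels do not say how many plants went into each library. The group of each library was taken from its labels, and each value column was assigned through the library code that the labels give.

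Reads were trimmed for quality and aligned with TopHat 2.0.12, and transcripts were quantified with Cufflinks and Cuffdiff 2.2.1 and inspected with cummeRbund 2.8.2, per the file headers. The genome was IRGSP-1.0 with the gene models of Ensembl Plants release 23, per the file headers, and the submitters' processing notes also name Cuffdiff and IRGSP-1.0. The deposited summary lists 82145342 reads for NT and 63341852 for PGD1:Roc10 before trimming, and 56985672 and 45354852 after it. Of the sequenced bases, 68.4% and 70.6% were kept. Mapped read pairs numbered 27683296 for NT and 21866514 for PGD1:Roc10, an alignment rate of 96.7% and 96.0%. The strand setting of the counting and the library normalization option are not given in the sources used here.

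The authors' main values are FPKM, fragments per kilobase of transcript and per 1000000 mapped fragments, with 76131 rows in the full table. FPKM carries no count per gene, so the depth behind a single value is unknown and no interval on single genes is given. An exact 0 in such a table can be a failed estimate, so a gene at 0 is said to be listed at 0 and no fold is given against it. The deposited p-value and q-value columns come from Cuffdiff run on 1 library per group, per the file headers, and were copied, never recomputed. A smaller sheet by the authors holds FPKM and a log2 fold change for 96 genes. Its log2 heading names other libraries, but in all 96 rows the deposited log2 value equals PGD1:Roc10 over NT within 0.001. The log2 columns of the full tables hold cells that are not numbers and were not used here. The deposited summary sheet also gives read and base numbers, which are used only for depth.

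No replicate exists in either group, so no test was made between the groups and differences were ranked by size alone. The difference of a gene is log2(FPKM + 1) in PGD1:Roc10 minus that in NT, which understates the change of genes with low values. Folds printed beside 2 FPKM values are their plain ratio. Rows with a mean FPKM of at least 1 over both libraries are called measured. Gene lists were fixed before the data were examined, as 27 sets of patterns on the symbols and descriptions that the table itself carries. For each list the share of measured members higher in PGD1:Roc10 has an exact (Clopper-Pearson) 95% binomial interval, which treats members as independent and describes these 2 libraries only. The median difference of each list was placed among 10000 random lists of the same size, drawn with replacement within 20 bins of mean FPKM from measured rows other than short RNAs. A list is said to stand apart when its median lies at or below percentile 2.5 or at or above percentile 97.5, which is a description and not a test. Some patterns took in genes of another kind, such as a WRKY factor in the HD-Zip IV list, and the values without them are given as an alternative chosen after the data were seen. Others missed genes of their kind that the table spells otherwise or names by symbol alone, and the lists corrected in both ways are a further alternative of this sort. The separate RefSeq gene table supplied as a reference was not used, since only 1 of the 35920 locus identifiers of the deposited table was found in it and it describes another assembly (ASM3414082v1).

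Genes are named by a rule fixed before the data were examined. It takes every HD-Zip IV gene, the 12 highest and 12 lowest differences among informatively described genes with a mean FPKM of at least 5, up to 3 measured members per list with the largest absolute difference, and the 10 genes per direction with the lowest q among those the authors call significant. Since the 12 highest and 12 lowest were non-coding rows, that part was repeated without non-coding rows after the data were seen. Any other gene named here was chosen after its values were seen. Coordinates are those of the deposited locus column on IRGSP-1.0. The sources used here do not say whether its starts count from 0 or from 1. The locus can span overlapping genes: 5001 measured rows share their locus with at least 1 other measured row.

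Alternatives were other pseudocounts (0.1, 0.5 and 5), 3 other scalings of the libraries, other filters on low values, other fold thresholds, stricter readings of the authors' calls, random lists not matched on expression, and lists without their most extreme member. The calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. They were tested on simulated libraries for PGD1:Roc10 against NT over 21875 rows, with an assumed log2 SD of 0.15 per library. With 100 genes raised by 1.5 on the log2 scale, 86% passed the 2-fold threshold. With 100 genes lowered by 3, 100% passed, and 0 unchanged genes did. That 0 rests on the small assumed SD, so it gives no rate of false calls for the real libraries. Between the real libraries, percentiles 2.5 and 97.5 of the differences were -0.67 and 0.88 for measured rows other than non-coding ones. For short RNA rows they were -9.47 and 12.5. How much of this spread is noise cannot be told with 1 library per group.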

Results

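Leaves of 2-week-old rice seedlings (Oryza sativa, cultivar Ilmi) grown under normal conditions were profiled by strand-specific RNA sequencing. The control was 1 library from nontransgenic plants (NT), and 1 library came from plants labelled PGD1:Roc10, in which a promoter described as active in the whole plant body drives Roc10. Roc10 belongs to the homeodomain-leucine zipper (HD-Zip) transcription factors, and the series title links it to lignin synthesis and to drought tolerance. The comparison therefore asks which leaf transcripts differ between plants that overexpress Roc10 and plants that do not. The NT library held 27683296 mapped read pairs and the PGD1:Roc10 library 21866514. With 1 library per group, no difference below has a replicate check, and none can be set against the spread between plants.

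In the PGD1:Roc10 library, transcripts of 8 of 52 measured WRKY transcription factors, which regulate plant defence genes, were at least 2-fold higher than in NT. Transcripts of 1 were 2-fold lower. The whole list of 128 defence genes gave 12 higher and 9 lower. Of the 8 WRKY genes, 4 lay below 1 FPKM in NT, and only the 2 named next were called significant in the authors' deposited table. WRKY factor 76 (OS09G0417600) stood at 91.9 FPKM against 10.3 FPKM, and a gene similar to WRKY factor 45 (OS05G0322900) at 249 against 37.5 FPKM. Among genes of the monolignol pathway, which makes the building blocks of lignin, CAD6 was 11.7-fold higher. A gene similar to phenylalanine ammonia-lyase (OS04G0518400) was 7.40-fold higher. Of the 38 measured genes matched to the pathway by name, some only as ligase-like, 21 were lower, none of them 2-fold. Stress genes went both ways: the salt-stress gene SALT (8.31 against 68.1 FPKM), the chitinase gene CHT5 and the dehydration-responsive gene LEA3 were lower, whereas CHT11 and the late embryogenesis abundant gene OS01G0705200 were 4.42-fold and 7.35-fold higher. The 48 measured ABA and dehydration genes gave 1 that was 2-fold higher and 5 that were 2-fold lower. Of 45 nuclear photosynthesis genes 1 differed 2-fold, as did 1 of 221 ribosomal protein genes and 0 of 11 clock genes.

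The transgene itself was looked for first, since it checks the labels. No row analysed here carries the name Roc10 in its symbol or description, so its level was not analysed here and the label of the PGD1:Roc10 library has no check from its own gene. The table names 11 other HD-Zip IV genes, the class of epidermal regulators to which the ROC genes belong, and 7 of these were measured. None of the 7 was 2-fold higher or lower, and 6 had the lower value in PGD1:Roc10. ROC2 (chromosome 4, 31900216 to 31907077) gave 39.2 FPKM against 48.7 FPKM in NT, and ROC5 (chromosome 2, 27487865 to 27494913) gave 33.4 against 36.4 FPKM. A gene similar to Roc1 (OS08G0187500) gave 20.2 against 22.7 FPKM. The ROC6-like OS09G0526200 gave 15.98 against 19.95 FPKM and the GLABRA2-like OS09G0526300 gave 12.8 against 19.3 FPKM. These 2 genes share 1 locus with each other (chromosome 9, 20568028 to 20574897), so that locus supplies 2 of the 7 measured genes. ROC2 and OS08G0187500 each share a locus with another measured row. The reads of all 4 may have been divided. ROC7 gave 3.98 against 4.77 FPKM, and ROC4, at 2.07 against 1.88 FPKM, was the 1 member with the higher value. TF1, ROC3 and ROC8 lay below 1 FPKM in both libraries, and ROC9 was listed at 0 in both.

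**Figure D1:**
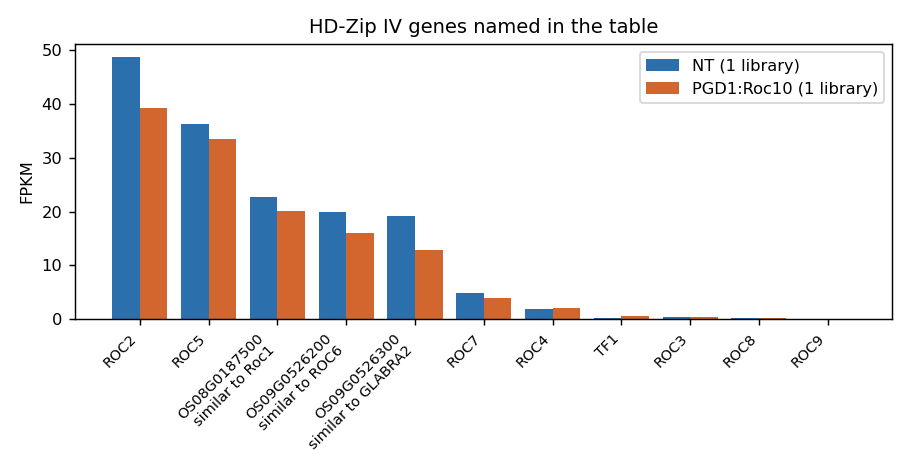
FPKM of the 11 HD-Zip IV genes named in the table, with 1 bar per library (blue, NT; orange, PGD1:Roc10) and no error bars, since each group has 1 library. ROC2 is the highest in both, at 48.7 FPKM in NT and 39.2 FPKM in PGD1:Roc10, and no measured member differs 2-fold.

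Counts of 2-fold differences are on the log2(FPKM + 1) scale throughout, so a gene with low values can have a plain ratio above 2 and not be counted. Over all 21875 measured rows, 502 were at least 2-fold higher in PGD1:Roc10 and 282 at least 2-fold lower, so 64.0% of the differing rows were higher. When both libraries were scaled to the same total FPKM, the median difference of all rows moved to -0.20 on the log2 scale and the split became 386 higher and 367 lower, or 51.3% higher. Short RNA rows carried 31.0% of all FPKM in PGD1:Roc10 and 18.1% in NT. The other rows summed to 837651 FPKM in PGD1:Roc10 and 857328 FPKM in NT. The shift under the same-total scaling therefore came from the short RNA rows. Of the 196 measured short RNA rows, 51 were 2-fold higher and 60 lower, and 49 were listed at 0 in NT and 49 at 0 in PGD1:Roc10. The 12 highest and the 12 lowest differences by the fixed rule were all non-coding rows, 11 of each being short RNAs. A row of the SNORD47 family (EPlOSAG00000009355), for example, was listed at 0 in NT and at 104053 FPKM in PGD1:Roc10, and a CC3510-family row (EPlOSAG00000015328) at 122807 FPKM and at 0. Without non-coding rows, 420 of 20702 rows were 2-fold higher and 191 lower.

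Among coding genes with a mean of at least 5 FPKM and a description of more than an unknown function, the highest difference belonged to a gene similar to an RNA-binding protein (OS12G0117700, chromosome 12, 871846 to 872269), at 270 FPKM against 4.13 FPKM in NT. An EF-hand protein gene (OS03G0812400), of a family that binds calcium, gave 59.2 against 0.710 FPKM. A pair of calmodulin binding protein-like genes had the same direction, OS08G0360300 at 26.0 against 0.123 FPKM and OS01G0134700 at 34.4 against 2.33 FPKM. WRKY factor 62 (OS09G0417800, chromosome 9, 14992942 to 14994888) gave 33.1 against 0.566 FPKM. A sesquiterpene synthase-like gene (OS08G0167800) gave 59.6 against 3.54 FPKM, and ARD1 gave 26.0 against 0.797 FPKM. An acetyltransferase-like gene (OS10G0503300) gave 27.9 against 0.805 FPKM, and OS04G0592600, which shares its locus with another row, gave 362 against 33.0 FPKM. The aspartic peptidase genes OS10G0537800 and OS10G0538200, neighbours on chromosome 10, gave 13.2 against 0.0904 FPKM and 14.1 FPKM against a listed 0. The RIR1b-like OS10G0569600 was also listed at 0 in NT and gave 12.2 FPKM.

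At the other end, a transferase-domain gene (OS06G0699100) was 12.9-fold lower in PGD1:Roc10, at 2.10 against 27.1 FPKM. SALT (chromosome 1, 13903284 to 13904626) was 8.19-fold lower. A thaumatin gene (OS12G0630200), of a family of pathogenesis-related proteins, was 15.8-fold lower at 0.666 against 10.5 FPKM. A protein kinase gene (OS01G0113800) gave 2.07 against 19.8 FPKM, and a UDP-glucosyltransferase gene (OS10G0178500) 2.11 against 19.6 FPKM. The chitinase-like OS04G0493400 and CHT5, both between 24687752 and 24709910 on chromosome 4, were 5.79-fold and 5.43-fold lower. A nearby lectin-like gene (OS04G0493600) was 6.57-fold lower. The proteinase inhibitor gene RBBI3.3 gave 1.80 against 11.6 FPKM, the benzoyltransferase-like OS11G0182200 gave 2.30 against 12.3 FPKM, and the germin gene GER5 gave 8.88 against 34.4 FPKM. The O-methyltransferase-like OS09G0344500 stood at 4.57 against 21.8 FPKM. Of the genes named here and below, OS06G0699100, 4CLL6, BC1L9, OS12G0559200, CYP74A1, PIP2-4, EXPA4 and OS05G0586300 each share a locus with another measured row, so their values are less certain.

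The authors' deposited table called 143 genes significant, 117 higher and 26 lower in PGD1:Roc10. Of these calls in the authors' deposited table, 38 were listed at 0 in NT and 9 at 0 in PGD1:Roc10, and the authors' shorter sheet held the other 96 genes, 79 higher and 17 lower. The lowest q in the authors' deposited table, 0.0111, was shared by 111 genes, so order within the calls followed the size of the difference. Among the 10 highest of these in the authors' deposited table was OS07G0162450, which carries a DUF3778 domain of unknown function and went from a listed 0 to 79.9 FPKM. Another DUF3778 gene, OS01G0108500, gave 84.8 against 4.02 FPKM with q = 0.0111 in the authors' deposited table. The other 8 were OS10G0538200 and 7 genes without an informative description. Among the 10 lowest in the authors' deposited table were SALT, OS04G0493400, CHT5, OS09G0344500 and a gene similar to a low-temperature induced protein (OS05G0122700), which was listed at 0 in PGD1:Roc10 and at 3.64 FPKM in NT. The largest fall among these 10 was in EPlOSAG00000008516 (chromosome 2, 28719356 to 28721172), at 1.59 against 114 FPKM in NT. This row has no description and was counted among the short RNA rows by its identifier alone. Another such row, EPlOSAG00000008521, was listed at 0 in PGD1:Roc10 and at 5.44 FPKM in NT. Many large differences carried no call: WRKY factor 62, 58.4-fold higher, had q = 0.770 in the authors' deposited table.

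**Figure D2:**
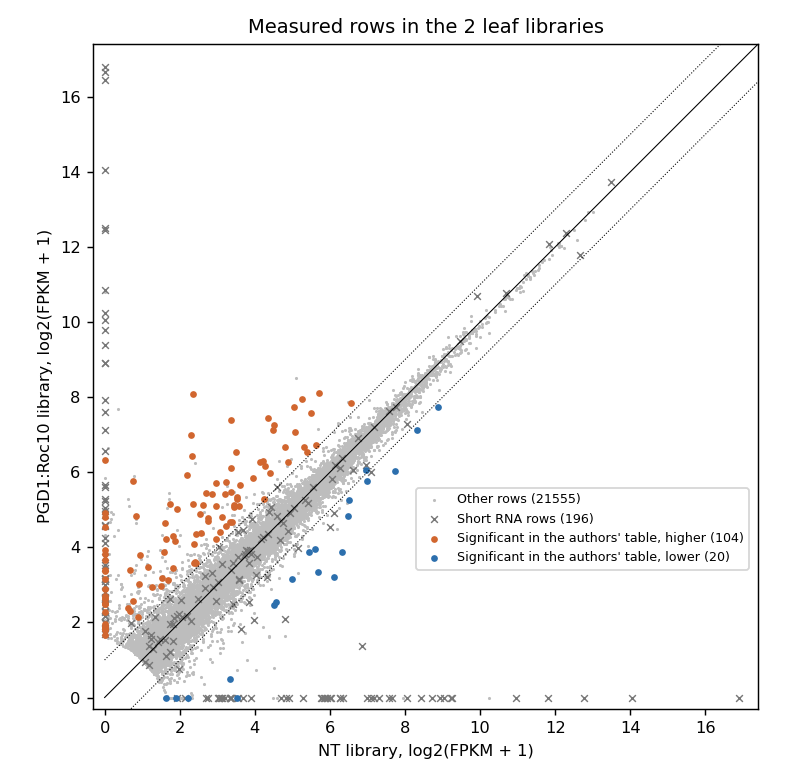
Log2(FPKM + 1) of the 21875 measured rows in NT (horizontal) and PGD1:Roc10 (vertical), with 1 point per row; the solid line marks equal values and the dotted lines 2-fold differences on this scale. Orange and blue points are rows called significant in the authors' deposited table, and crosses are the 196 short RNA rows, many of which lie on an axis because 1 library is listed at 0.

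The lignin-related lists held a few large single differences. Of 38 measured monolignol genes, 17 were higher (44.7%, exact 95% interval 28.6 to 61.7%), 3 of them at least 2-fold, and none was 2-fold lower. The 3 were CAD6 (chromosome 4, 8637313 to 8639345), a cinnamyl alcohol dehydrogenase gene at 24.0 against 2.05 FPKM, the phenylalanine ammonia-lyase-like OS04G0518400 at 18.5 against 2.51 FPKM, and the 4-coumarate:CoA ligase-like 4CLL6 at 9.62 against 2.74 FPKM. The median difference of the list, -0.04, lay at percentile 24.5 of matched random lists. The most abundant member, the 4-coumarate-CoA ligase-like OS04G0683700, gave 635 against 955 FPKM. The 38 include genes named only as 4-coumarate:CoA ligase-like, such as this gene and 4CLL6. They also include genes similar to hydroxyanthranilate hydroxycinnamoyltransferase. The descriptions do not show that these act in the pathway, and the list was not repeated without them. The patterns for O-methyltransferases outside that pathway found 6 measured genes, of which 1 was higher and OS09G0344500 was 2-fold lower. They missed 4 genes by spelling or symbol, and with these 5 of 10 were higher, 1 at least 2-fold. That gene, OS04G0175600, gave 39.9 against 10.5 FPKM, with q = 0.0111 in the authors' deposited table. The other 3 were ROMT-9, ROMT-15 and ROMT-17. Class III peroxidases, which can oxidise monolignols, had 22 of 44 members higher, none 2-fold higher and 3 2-fold lower, OS06G0547400, OS01G0326300 and OS04G0688300. The 44 include 7 phosphatases named with haloperoxidases, and without them 16 of 37 were higher. Of the laccases and dirigent proteins only LAC7, at 78.8 against 124 FPKM, and LAC4, at 1.42 against 0.888 FPKM, were measured. The secondary wall list stood apart upward, with 8 of 9 members higher (88.9%, 51.8 to 99.7%), a median of 0.31 and percentile 99.6, though none was 2-fold higher on the log2(FPKM + 1) scale. BC1L9 gave 2.02 against 0.649 FPKM, a plain ratio of 3.11, and BC1L4 22.9 against 16.9 FPKM. Of the cellulose synthase genes in that list, CESA4 gave 4.46 against 3.62 FPKM. CESA7, the 1 member that was lower, gave 2.96 against 3.35 FPKM.

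Drought and surface lists went in different directions member by member. Of 48 measured ABA and dehydration genes, 26 were higher (54.2%, 39.2 to 68.6%), 1 at least 2-fold, and 5 were 2-fold lower. The late embryogenesis abundant repeat gene OS01G0705200 gave 68.5 against 9.32 FPKM, whereas LEA3 gave 3.79 against 14.7 FPKM, RAB21 6.35 against 20.5 FPKM and a drought-tolerance NAC gene (OS11G0126900) 0.469 against 4.97 FPKM. RAB16B, at 0.839 against 3.21 FPKM, and the late embryogenesis abundant gene OS04G0589800, at 1.27 against 3.90 FPKM, were also 2-fold lower. A dehydrin family gene (OS02G0669100) gave 101 against 100 FPKM. Outside the measured rows, LEA1 was listed at 0 against 1.77 FPKM in NT and was called significant in the authors' deposited table. The median of this list was 0.02 as deposited and -0.17 after scaling to the same total, where the median of all rows was -0.20. With 7 genes that the patterns missed, 32 of 55 were higher, with a median of 0.05 at percentile 95.5 in place of 76.6. In the cuticle and wax list 4 of 14 members were higher and none differed 2-fold, with a median of -0.13 at percentile 3.89. The list took in CERK1, a chitin receptor kinase, and lay at percentile 14.4 without it. Without 2 membrane lipid acyltransferases as well it lay at percentile 2.88. Lipid transfer proteins stood apart downward, with 13 of 31 higher, none 2-fold on that scale, a median of -0.19 and percentile 0.02. Without 3 glycolipid transfer proteins 11 of 28 were higher. Without a filter on low values, or above 5 FPKM, that list lay at percentiles 66.5 and 3.69. Aquaporins had 12 of 26 higher, or 10 of 21 without 5 proteins of another kind, and PIP2-4, at 16.04 against 5.50 FPKM, was the 1 that was 2-fold higher.

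Of 128 measured defence genes, 61 were higher (47.7%, 38.8 to 56.7%), 12 at least 2-fold, and 9 were 2-fold lower. The authors' deposited table called 5 of the 12 and 4 of the 9 significant. Within the list the 52 WRKY genes gave 8 that were 2-fold higher and 1 lower. The other 76 genes, such as chitinases, glucanases and thaumatins, gave 4 higher and 8 lower. This split was not among the lists fixed beforehand. Those 76 include 15 AP2/ERF factors, none of which differed 2-fold, and without them 56 of 113 genes of the list were higher. Of the 8 WRKY genes, 4 lay below 1 FPKM in NT and 4 at 1 FPKM or more. The lowest of these in NT, the WRKY 17-like OS03G0335200, gave 8.69 against 0.103 FPKM. CHT11 gave 77.5 against 17.5 FPKM, opposite to CHT5 at 9.23 against 50.1 FPKM. The median of the list, -0.03, lay at percentile 16.1, and without the AP2/ERF factors at percentile 58.5. The patterns missed RBBI3.3, and with it 10 were 2-fold lower. The jasmonate list, of genes for this wound and defence hormone, stood apart upward, with 18 of 23 members higher (78.3%, 56.3 to 92.5%), a median of 0.31 and percentile 100. It took in 2 potassium channel genes, and without them 16 of 21 were higher (76.2%, 52.8 to 91.8%), at percentile 100. With 2 genes that the patterns missed, CYP74A1 and CM-LOX1, added to these it was 17 of 23. Its 2 members at least 2-fold higher were a lipoxygenase-like gene (OS12G0559200), at 101 against 38.9 FPKM, and a jasmonate-induced protein-like gene (OS10G0132300), at 26.7 against 5.62 FPKM. In the diterpenoid phytoalexin list, 6 of 7 members were higher, with a median of 0.29 and percentile 98.7. Its 1 member at least 2-fold higher, OS08G0167800, is a sesquiterpene synthase-like gene and not a diterpene enzyme. Without it 5 of 6 were higher, at percentile 97.9. Without a filter on low values the list, then 21 genes, had a median of 0.07 at percentile 94.6. CPS2 gave 5.59 against 3.37 FPKM.

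**Figure D3:**
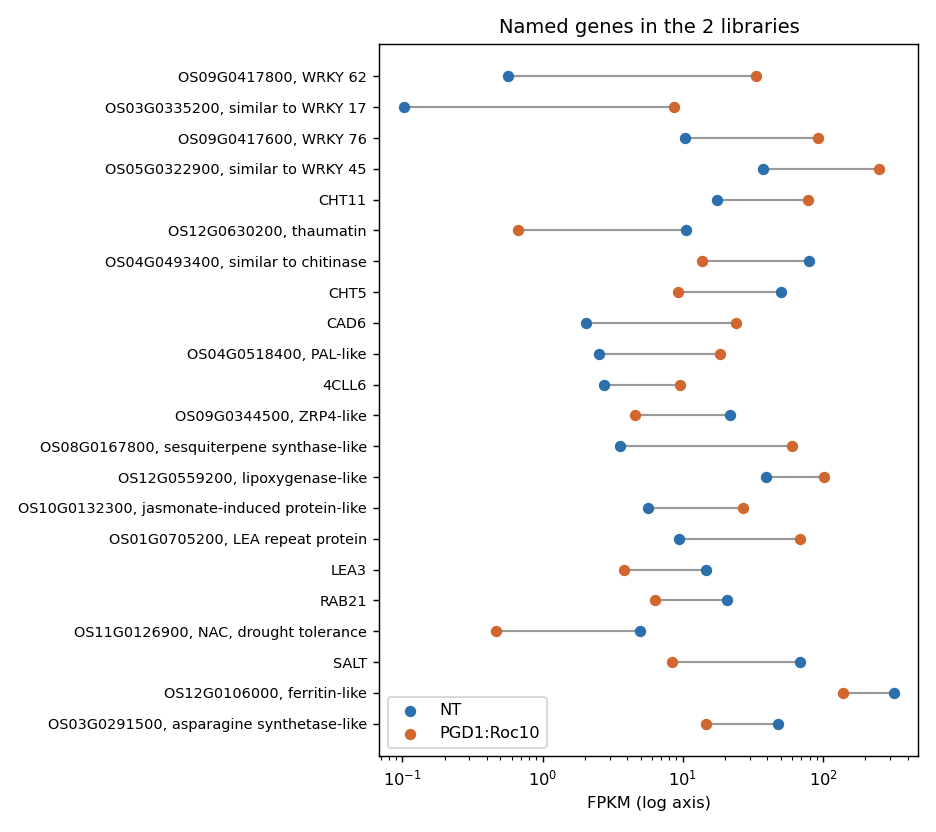
FPKM on a log axis of 22 named genes in NT (blue) and PGD1:Roc10 (orange), with 1 point per library and a line joining the pair. The genes are chosen examples and do not stand for their families: the WRKY, CAD6, phenylalanine ammonia-lyase-like and sesquiterpene synthase-like genes shown lie to the right in PGD1:Roc10, and SALT, CHT5, LEA3 and RAB21 lie to the left.

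Growth, light and nutrient lists held few 2-fold differences. Of 45 measured nuclear photosynthesis genes 11 were higher (24.4%, 12.9 to 39.5%), and OS07G0147550, a photosystem II polypeptide-like gene at 32.2 against 75.2 FPKM, was the 1 that differed 2-fold. The median was -0.08 at percentile 6.75, and with 2 missed genes the list lay at percentile 11.1. No clock gene differed 2-fold, and PRR95, at 226 against 280 FPKM, differed most among the 11 measured. With the missed PCL1, 3 of 12 clock genes were higher. Auxin response genes stood apart downward, with 22 of 62 higher, none 2-fold on the log2(FPKM + 1) scale, a median of -0.08 and percentile 1.11, and above 5 FPKM they lay at percentile 4.98. IAA1 gave 43.0 against 78.2 FPKM and IAA9 1.63 against 3.86 FPKM, 2.37-fold lower as a plain ratio. Without 1 gene of another kind the list lay at percentile 1.27. Of 14 expansin and growth genes 6 were higher, and EXPA4, at 5.65 against 14.7 FPKM, was 2-fold lower. The list as matched lay at percentile 6.89, and above 5 FPKM its 6 genes lay at percentile 0 with a median of -0.68. With 5 missed expansin-like genes 9 of 19 were higher, at percentile 9.76. Metal and phosphate genes had 19 of 39 higher, or 15 of 32 without 7 genes of another kind and 28 of 55 with 23 that the patterns missed, with a ferritin-like gene (OS12G0106000) at 139 against 320 FPKM and a ferritin family gene (OS01G0508100) at 6.94 against 1.28 FPKM. Nitrate and ammonium genes had 12 of 26 higher, or 12 of 25 without 1 gene of another kind and 13 of 27 with 2 missed genes, among them the nitrate transporter-like OS01G0547600 at 8.37 against 1.92 FPKM, while an asparagine synthetase-like gene (OS03G0291500) gave 14.6 against 47.5 FPKM.

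Lists meant to show another tissue or general stress were mostly flat. Heat shock proteins and chaperones had 80 of 156 members higher, with HSP17.9A, at 28.2 against 59.6 FPKM, the 1 that was 2-fold lower. Histone and cell division genes had 39 of 69 higher, and ribosomal proteins 105 of 221, with 1 member of each list 2-fold higher. Without 12 genes of another kind, mostly organelle-type, 99 of 209 ribosomal protein genes were higher. With missed genes added the counts were 82 of 159 for heat shock, 45 of 81 for histone and 104 of 227 for ribosomal protein genes. Of 34 genes in the shoot apex and other organ list, 20 were higher. Of the 34, 14 are genes of another kind, such as chromosome condensation regulators, and 11 of the other 20 were higher. The medians of the heat shock, histone and shoot apex lists lay above 0 as deposited and below 0 after scaling to the same total, where the median of all rows was -0.20. They stayed above that median, at percentiles 82.5, 91.5 and 81.9. MADS1, at 4.52 against 0.312 FPKM, and an OSH10-like gene (OS03G0673000), at 2.63 FPKM against a listed 0, were 2-fold higher. The FAMA-like OS05G0586300, at 3.32 against 3.75 FPKM, was 1 of 2 measured members of the guard cell list, and the other is a stomatin-like gene of another kind. Transposon-related rows had 13 of 37 higher, 1 of them 2-fold. No row lay on an organelle genome, so the plastid and mitochondrial list had 0 members. Reference genes had 24 of 36 members higher (66.7%, 49.0 to 81.4%), none 2-fold, with a median of 0.07 at percentile 98.5. After scaling to the same total their median was -0.10, still above that of all rows, at percentile 99.15. As deposited but without 12 genes of another function, 15 of 24 were higher, at percentile 96.6. With 10 missed genes added to these as well, 23 of 34 were higher (67.6%) at percentile 99.4. HD-Zip IV genes, as matched with 1 WRKY factor among 8 members, stood apart downward with a median of -0.19 at percentile 1.76, and without that factor at percentile 2.04. Without their most extreme member they lay at percentile 5.42. That member, OS09G0526300, shares its locus with another member, OS09G0526200.

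**Figure D4:**
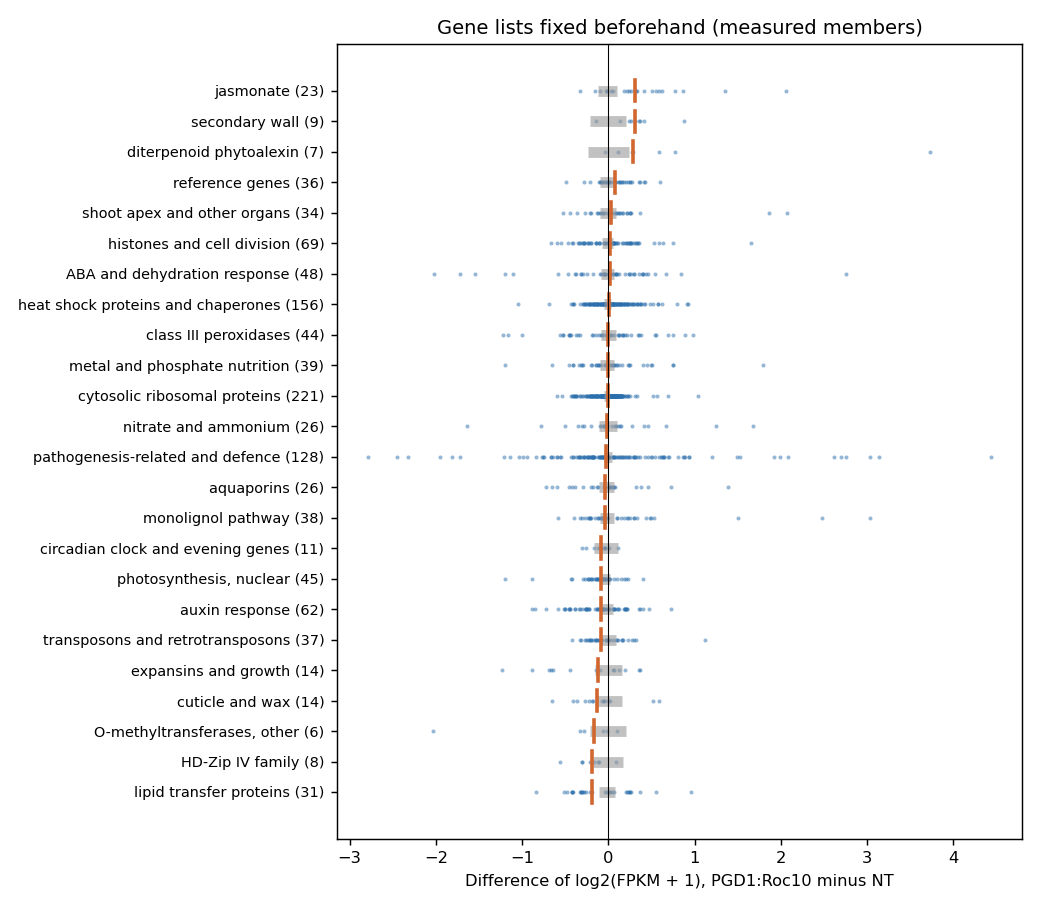
Difference of log2(FPKM + 1), PGD1:Roc10 minus NT, for the measured members of each gene list as matched, with at least 3 such members (blue points; number in brackets); orange bars are list medians and grey bands the central 95% of medians of 10000 matched random lists. The jasmonate, secondary wall and diterpenoid phytoalexin medians lie to the right of their bands, at 0.31, 0.31 and 0.29 for measured rows, and the reference gene median just so. The lipid transfer protein, HD-Zip IV and auxin response medians lie to the left, at -0.19, -0.19 and -0.08.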

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

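Of the alternatives, leaving out non-coding rows, keeping 1 row per locus and dropping list members of another function, alone or with missed genes added, were chosen after the data were seen, and the rest before. No paired analysis was possible because each group holds 1 library. Keeping only rows that Cuffdiff could test changed nothing, since every measured row is one. Of 864 values of 144 named genes under 6 alternatives, 37 crossed the 2-fold line and none went from 2-fold higher to 2-fold lower or back. That none did could hardly be otherwise. Pseudocounts keep the sign of a difference, and the scalings moved the median of all rows only to 0.005, -0.20 and -0.01. Small differences could change sign, as that of ROC4 did at the same total. The share of HD-Zip IV genes at least 2-fold higher was 0 throughout. Depth per gene is unknown. The 502 higher and 282 lower rows became 214 and 100 with pseudocount 5, 249 and 138 above a mean of 5 FPKM, 258 and 132 where both libraries reached 1 FPKM, 1122 and 856 at 1.5-fold and 182 and 88 at 4-fold, since each of these by construction admits fewer or more rows. With pseudocount 0.1 the lower rows numbered 483. Of the calls in the authors' deposited table, 0 higher and 0 lower had q of 0.01 or less. The lowest q there, 0.0111, was shared by 111 genes, so that bound removes every call whatever its size. It therefore says nothing on how firm the calls are. Among the calls, 70 higher and 16 lower genes reached 1 FPKM in both libraries.

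Short RNA rows summed to 375884 FPKM in PGD1:Roc10 and 189933 FPKM in NT, and the other rows to 837651 and 857328 FPKM. Because of the short RNA rows, scaling to the same total FPKM moved the median of all rows to -0.20 and with it the percent of members higher. That percent became 0 for HD-Zip IV genes, other O-methyltransferases, clock and guard cell genes, 26.2 for peroxidases, 31.3 for ABA, 36.3 for defence, 4.44 for photosynthesis, 18.7 for heat shock, 27.3 for histones, 4.55 for ribosomal proteins, 13.3 for auxin, 25.6 for metal, 23.1 for nitrate, 20 for aquaporins, 23.5 for shoot apex, 13.5 for transposons and 25 for reference genes. Of the lists that kept their interval, the percent was 50 for laccases, as before, 87.5 for secondary wall genes, 14.3 for cuticle, 26.7 for lipid transfer, 21.4 for expansins, 30.6 for monolignol, 63.6 for jasmonate and 71.4 for phytoalexin genes. Above a mean of 5 FPKM it was 0 for HD-Zip IV genes and laccases, 100 for secondary wall, phytoalexin and guard cell genes, and 16.7 for expansins, with fewer members. Where both libraries reached 1 FPKM it was 0 for laccases. Without the most extreme member it was 100 for laccases and for guard cell genes, each then 1 gene, and without members of another function 0 for guard cell genes.

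Percentiles that crossed a bound are given next, and the cause was not tested. HD-Zip IV genes lay at 2.66 with pseudocount 5, 2.66 at the same total, 6.47 without a filter, 3.05 against unmatched lists and 5.42 without the most extreme member. Without a filter, peroxidases lay at 2.27, lipid transfer proteins at 66.5, defence genes at 0.26 and phytoalexin genes at 94.6. The defence values here and above 5 FPKM include AP2/ERF factors. Leaving these out moved the list from 16.1 to 58.5 under the main settings. Above 5 FPKM, laccases lay at 1.30, cuticle genes at 0.59, lipid transfer proteins at 3.69, defence genes at 2.00, expansins at 0, auxin genes at 4.98 and transposons at 1.91. With 1 FPKM in both libraries, laccases lay at 0.73 and cuticle genes at 1.13. These cuticle values include CERK1, a receptor kinase, without which the list lay at 14.4 under the main settings. Without 2 membrane lipid acyltransferases as well it lay at 2.88. Transposons lay at 1.31 with pseudocount 5 and 1.27 at the same total. Reference genes lay at 97.2 with pseudocount 5, 94.4 after quantile normalization, 96.4 against unmatched lists and 96.6 without members of another function, but at 99.4 with missed genes added as well. Jasmonate and secondary wall genes stood apart upward under all alternatives run.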

Other observations

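The families in the next sentences, the locations of neighbouring genes, and the tests on the hour of harvest, on plants and pots, on unnamed rows and on exchanged labels were chosen after the values were seen. The recounts under other scalings, per locus and per family were set before their outcome was seen, but after the pattern itself.

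Among 113 measured NB-ARC or NBS-LRR genes, the intracellular immune receptors of plants, 12 were at least 2-fold higher and 0 lower (10.6%, exact 95% interval 5.61 to 17.8%), against 407 of 19459 described coding rows (2.09%). OS11G0226933 gave 34.0 against 9.89 FPKM and OS11G0229300 4.94 against 0.694 FPKM. Of 13 calmodulin binding protein-like genes, 6 were 2-fold higher, and 7 of 22 AAA-type ATPase genes were, among them the BCS1-like OS01G0605100 at 42.0 against 6.24 FPKM. The calcium pump gene OS03G0203700 gave 19.7 against 4.96 FPKM, and the wall-associated kinase-like OS09G0471400 gave 19.3 against 4.43 FPKM. Of 20 EF-hand genes 1 was 2-fold higher (5%, 0.127 to 24.9%), with a median difference of 0.006 at percentile 67.1. Of 113 cytochrome P450 genes 3 were 2-fold higher and 1 lower, and of 20 chitinase genes 3 were higher and 4 lower. Members of such families resemble each other, and reads shared between copies were not separated here. OS03G0203700, OS09G0471400 and AGO18 also share a locus with another measured row. AGO18, an Argonaute gene, gave 9.54 against 0.583 FPKM. Among homeodomain genes, HOX24 gave 1.26 against 7.46 FPKM and HOX12 0.109 against 2.07 FPKM, and of 94 measured rows with a homeodomain or START description 1 was 2-fold higher and 3 were 2-fold lower.

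The first pattern is the group of 12 defence-list genes that were at least 2-fold higher in PGD1:Roc10, 8 of them WRKY factors, while 9 others were lower. Of the 12, 5 were called significant in the authors' deposited table. All 12 of the 12 stayed 2-fold higher under each of 3 other scalings, so the count does not depend on the choice among these. The smallest of the 12 differences was 1.21 (OS01G0944900), and the scalings moved the median of all rows only to 0.005, -0.20 and -0.01. They could thus hardly bring a gene below 2-fold, and this recount draws no conclusion on the scaling by the authors. A different hour of harvest is argued against, because the 11 measured clock genes differed by at most 0.30 on the log2 scale. Such genes swing widely within a day. Whether the genes are higher because of the transgene or because the plants or pots sampled differed, for example in exposure to a pathogen, cannot be told apart with 1 library per group. Roc10 overexpression may thus account for the pattern, and this stays an untested hypothesis.

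The second pattern is that none of the 7 measured HD-Zip IV genes named in the table was at least 2-fold higher in the library of a HD-Zip overexpressor. Of 94 measured rows with a homeodomain or START description, 1 was 2-fold higher and 3 were 2-fold lower. None of the 94 was 2-fold higher with at least 5 FPKM in PGD1:Roc10. The transgene may be counted in a row that carries no HD-Zip IV name: 57 rows without an informative name were at least 4-fold higher at 5 FPKM or more in PGD1:Roc10. No value singles out 1 of them, so this stays open. Exchange of the 2 labels also stays open, since no row is named for the transgene. The lowest difference of a measured HD-Zip IV gene, -0.56, is short of 2-fold. These genes are not the transgene, so their values cannot decide it. All directions above therefore rest on the labels alone.

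The third pattern is that genes at least 2-fold higher in PGD1:Roc10 lie near each other: 165 of 420 coding rows had another such row starting within 100 kb, against 80 to 125 in the central 95% of 1000 random sets matched on expression. Reads shared between overlapping rows are argued against as the whole cause, since with 1 row per locus 127 of 386 genes were still so placed, above the highest random set (123). Neighbouring members of 1 gene family may account for part of the rest. With 1 gene kept per shared description within 100 kb the number was 121 of 381, above the central 95% (63 to 105) but not above the highest random set (122), which leaves this open. That step removed few genes, from 386 to 381. Relatives with differing descriptions, such as the RIR1a and RIR1b-like genes named below, were not merged by it. A chromosome segment that differs between the plants, or co-regulated neighbours, were not tested.

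Examples of such neighbours are 3 NB-ARC or NBS-LRR genes between 6827132 and 6884768 on chromosome 11, 2 WAK80-like kinase genes with 1 gene between them from 17960281 to 18008036 on chromosome 9, and 6 genes from 22516056 to 22608671 on chromosome 10. The last group includes OS10G0569400, the RIR1a precursor gene, at 212 against 31.7 FPKM, and the RIR1b-like OS10G0569600. A further 6 genes, none with a known function in the table, lie between 2436923 and 2482637 on chromosome 5.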
